A study of Homo sapiens with 3 samples.

How the data were processed

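Gene expression was measured on 3 arrays of 1 colour, 1 for each of wild-type Ca9-22, SLPI-deficient Ca9-22 and HT-29 cells as the labels name them. Per the labels' protocols, the dishes were grown for 3 days in the same serum-containing medium, and Cy3-labelled cRNA was made from 50 ng of total RNA. Each group is 1 sample, and the labels give no replicate culture. The 3 arrays lay on the same slide, so no slide effect could separate the groups. No position or label told which part of SLPI was altered in the deficient cells.

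Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1 on array design 039494. The deposited processed signal is an intensity on a linear scale, which that software background-subtracted and corrected for spatial trends, with substitute values for spots not above background. The mean pixel signal and the median signal of the local background, also deposited as intensity, carry no such correction. The spot flags are other values of 0 or 1, per the file headers. The value table deposited with the series holds a linear intensity too. Set against the scanner files, each of its columns equalled that array's processed signal divided by 1 constant (237.858 for wild-type Ca9-22, 276.693 for the array labelled SLPI-deficient Ca9-22 and 340.53 for HT-29). These constants lay at the array's 75th percentile over all features, control spots included. The column medians were 0.0685, 0.0540 and 0.0492 in the same order, and scale, centring and direction of the table are therefore known.

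Each array held 58717 spots that were not controls, for 50599 probes. Log2 of the processed signal was taken minus the array's 75th percentile over these spots. Spots carrying an outlier flag were left out (371, 345 and 344 on the 3 arrays), which dropped 24 probes, and the remaining spots of a probe were averaged. No spot was saturated. Gene names come from the scanner files and were updated through a RefSeq gene table of assembly GRCh38.p14, used for names only: 30004 probes matched by accession, 3112 by symbol and 487 by synonym, 8928 kept the name in the file and 8068 had no gene name. The genome build of the probe positions in the files is not given in the sources used here.

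Of 28688 named genes, 17500 had a probe well above background on at least 1 array and were kept, 14014 of them protein coding. A gene took the value of its probe with the highest mean over the 3 arrays among such probes. A comparison covered genes well above background on at least 1 of its 2 arrays. Where a gene was dim on 1 of them, its fold is a bound: the bright value against the higher of the dim array's lowest signal well above background and the probe's own value, written "at least". A bound was never taken past 1-fold. Genes whose chosen probe was dim on an array where another of their probes was bright were left out of that comparison (64, 61 and 33 genes). A gene was counted as higher or lower at 2-fold or more.

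With 1 array per group there is no test between groups and no p-value. The errors that could be measured were those within an array. Over the 902 probes printed on several spots, the median SD between spots was 0.081, 0.070 and 0.066 on the log2 scale for probes well above background on the wild-type, labelled SLPI-deficient and HT-29 arrays. For dim probes it was 0.25, 0.27 and 0.28. The number of arrays limits the precision of every value.

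The arrays were compared in 3 pairs. A set of 32 gene lists was fixed before the data were examined, as were the rule for named genes, the rule of size and all but 1 of the alternatives. The lists cover squamous and intestinal epithelium, HOX genes, mucins, protease inhibitors, matrix proteases, matrix, adhesion, junctions, mesenchymal genes, motility, innate defence, cytokines, interferon and MHC genes, signalling pathways, cell cycle, metabolism, stress, metallothioneins, ribosomal proteins, reference genes and markers of fibroblasts, blood and endothelial cells. For a list with at least 5 measured members, the median log2 difference was set against 10000 random lists of the same size matched on mean expression, in 20 bins. Its percentile describes these arrays and is no test of the cell types. Some lists share members, such as the intestinal and mucin lists, so agreement between such lists is not independent. A bounded median is the same median with genes dim on 1 array at their bound.

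Named genes were, in each pair, the 10 highest and 10 lowest differences among genes well above background on both arrays and the 5 highest and 5 lowest bounds. From each list came up to 4 members with the largest difference of at least 2-fold, or up to 2 with the highest mean where none reached it. SLPI was always named, and Y-linked genes and names that are only accessions were left out.

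Both differences from wild-type Ca9-22 use the same array. Their overlap was set beside that of independent lists and beside 100 simulated draws in which nothing but spot noise differed. The alternatives were normexp background correction with offset 50, quantile normalization, centring on the median of all probes or of probes above background on all arrays, the deposited value table, stricter and no filters on dim probes, the mean of a gene's probes, and thresholds of 1.5-fold and 4-fold. Choosing each probe without the labelled SLPI-deficient array was added after seeing the data.

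The counting rule was tested on simulated data for the comparison of labelled SLPI-deficient with wild-type Ca9-22, over 15061 genes. It recovered 95% of the simulated genes changed by 1.5 on the log2 scale and 97% of those changed by 2.5, and called 0 of 14861 unchanged genes. The simulated arrays were copies of the wild-type array with spot noise only, which is small beside 2-fold. The 0 calls were therefore nearly fixed in advance and give no rate of false calls between cultures. Of 50 random lists with no shift, 46 lay inside the central 95% range. The work used R 4.3.3 with limma 3.58.1 and data.table (1.17.8), and python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.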

Results

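RNA from 3 cultures of human carcinoma cell lines was hybridised to 1 array each. Ca9-22 is a line from a gingival squamous cell carcinoma and was used as wild type and as a derivative labelled SLPI-deficient. HT-29 is a line from a colorectal adenocarcinoma. SLPI, secretory leukocyte peptidase inhibitor, is a small secreted protein that blocks neutrophil elastase and related serine proteases. By its title, the series set the lines side by side to look into cell migration linked to SLPI. The 75th percentile of the processed signal was 272.01 on the wild-type array, 324.96 on the labelled SLPI-deficient array and 395.85 on the HT-29 array, and 22663, 22765 and 23771 probes were well above background. Each group had 1 array, so no difference below has a replicate check.

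SLPI was read by 1 probe on 1 spot, at chromosome 20, positions 43882220 to 43882279 as the files give them, in a genome build not given in the sources used here. Its processed signal was 3336 in wild-type Ca9-22, 998.9 on the array labelled SLPI-deficient and 290.6 in HT-29, well above background on all 3. After scaling, SLPI was 3.99-fold lower on the array labelled SLPI-deficient than in wild-type Ca9-22 (log2 difference −2.00). It was 16.7-fold lower in HT-29 than in wild-type Ca9-22 (−4.06), and 4.19-fold lower in HT-29 than on the array labelled SLPI-deficient (−2.07). The SD expected from spots alone was 0.107, 0.105 and 0.096 for these differences. The labels do not say which part of the gene was altered, so a probe outside that part would not check the label. HT-29, which carries no such label, had lower SLPI still, and the labelled array had HT-29-like markers (below). Its lower SLPI therefore cannot tell loss of SLPI from a difference between lines.

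The cell type markers went against the label. On the array labelled SLPI-deficient Ca9-22, 21 of the 48 squamous genes on the array design were well above background, against 41 in wild-type Ca9-22 and 25 in HT-29. Of 66 intestinal genes, 46 were well above background there, against 23 in wild-type Ca9-22 and 50 in HT-29. It is therefore called the array labelled SLPI-deficient throughout, and every direction taken from it rests on that label.

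**Figure D1:**
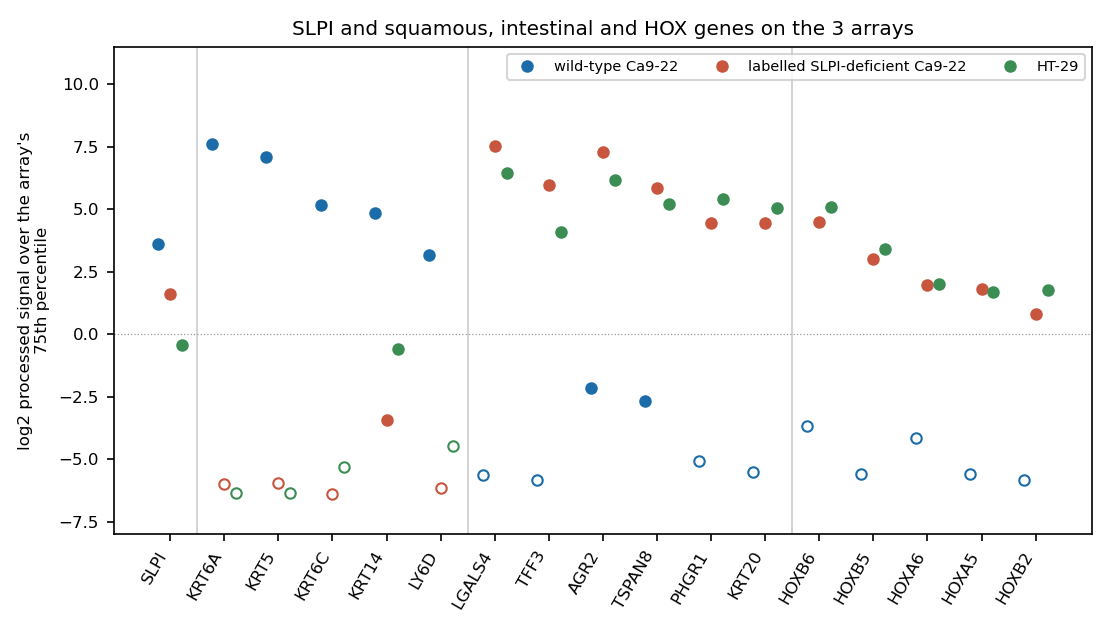
Log2 processed signal over the array's 75th percentile (y axis) for SLPI and for named squamous, intestinal and HOX genes (x axis, separated by grey lines). Each point is 1 array, and open points are not well above background; KRT5 and KRT6A were above background in wild-type Ca9-22 alone, while LGALS4, KRT20 and HOXB6 were above background on the other 2 arrays.

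The first comparison asked how the SLPI-deficient derivative differed from wild-type Ca9-22. The array labelled SLPI-deficient had low keratins of stratified epithelium and high genes of the intestinal lining. KRT6A and KRT5, keratins of stratified squamous epithelium, were at least 3244-fold and at least 2289-fold lower, and neither was well above background there. LGALS4, a galectin of the gut epithelium, was at least 2411-fold higher, and the goblet cell peptide TFF3 at least 818-fold higher. In all, 2891 genes were at least 2-fold higher and 3461 at least 2-fold lower of 16686 compared, or 38.1%.

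Of 42 measured squamous genes, 34 were lower, 1 was higher and 7 were counted as neither. The median log2 difference was −4.43 (bounded median −3.56), at percentile 0 of random lists. KRT14 was 308-fold lower, and KRT17 and S100A2 were 288-fold and 274-fold lower. The probes of KRT14, TFF3, REG4 and COL5A1 gave differing sizes, with log2 differences of −8.27 to −4.68, 5.04 to 11.81, 8.14 to 10.44 and −7.12 to −5.56. The KRT5 probe lies at chromosome 12, positions 52908622 to 52908681 in the files. Of 48 measured intestinal genes, 35 were higher and 3 lower, with a median of 4.09 (bounded 3.36). TSPAN8 was 374-fold and AGR2, a disulfide isomerase of secretory cells, 702-fold higher. Among 21 mucin and secretory genes, 14 were higher and 3 lower (median 3.53, bounded 3.13), with REG4 at least 369-fold higher. REG4, TFF3 and AGR2 are members of the intestinal list too. HOX genes, which mark position along the body axis, were higher in 19 of 29 cases and lower in 6 (median 3.75, bounded 2.97). HOXB6 and HOXB5 were at least 287-fold and at least 105-fold higher.

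The genes with the highest differences measured on both arrays were S100P, a calcium-binding protein, at 1913-fold, CLDN3, a tight junction claudin, at 814-fold, AGR2 and TSPAN8. ADIRF (718-fold), ADA (401-fold), which encodes adenosine deaminase, and KRT14 were lowest. SPINK1, a secreted trypsin inhibitor, was at least 3547-fold higher. ANXA8L1 had the lowest bound (at least 14136-fold), but near-identical annexin copies exist, so its identity is uncertain, as is that of KRT6A against KRT6C.

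Of 32 protease inhibitors measured, 12 were higher and 13 lower, with a median of 0.10 at percentile 66.2, which was −0.27 with no filter on dim probes and 0.79 with only genes above background on both arrays. Cystatin A, CSTA, was at least 175-fold lower and TFPI at least 110-fold higher. Matrix proteases were higher in 12 and lower in 21 of 44 cases (median −0.74, bounded −0.51, percentile 0.10). MMP7, matrilysin, was at least 768-fold higher, and the collagenase MMP1 at least 644-fold lower. Matrix and matricellular genes were lower in 25 and higher in 7 of 38 cases (median −2.84, bounded −2.41). COL7A1, the anchoring fibril collagen, was at least 147-fold lower and COL5A1 139-fold lower. Mesenchymal genes and regulators of epithelial-mesenchymal transition were lower in 17 and higher in 4 of 28 cases (median −2.83, bounded −1.74). Integrins and adhesion receptors had a median of −0.68, with ITGA5, the fibronectin receptor subunit, 15.0-fold lower. In the motility list, 23 of 64 genes were lower and 9 higher; its median of −0.32 turned to 0.06 with arrays centred on their medians. Junction genes went both ways (16 higher, 10 lower of 43, median 0.21, or 0.054 to 0.59 over all settings), with the desmosomal cadherin DSG3 at least 127-fold lower.

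Interferon-stimulated genes were lower in 23 and higher in 4 of 47 cases (median −1.23, bounded −0.98), among them IFI44 at least 163-fold lower. MHC and antigen presentation genes had a median of −0.85, with 11 of 23 lower. In the metallothionein list, which includes the zinc exporter SLC30A1, 8 of 10 measured genes were lower and 0 higher (median −3.12). MT2A was 88.4-fold lower, but the MT1 genes are near-identical and cannot be told from one another by these probes with certainty. The list called EGF pathway here holds EGF-family receptors and ligands and ERK feedback genes. It also holds other growth factor and receptor genes, such as MET, AXL, PDGFA and VEGFC, so it is no pure EGF list. Its median was 1.38 (bounded 1.16), with 21 of 39 higher and 10 lower. VEGFC, a vascular growth factor, and the phosphatase DUSP10 were at least 36.3-fold and at least 34.6-fold lower, and EREG, epiregulin, at least 25.5-fold higher. Ribosomal protein genes had a median of 0.85, with 18 of 44 at least 2-fold higher and 0 lower. Sterol and lipid synthesis genes had a median of 0.73, and NRF2 and xenobiotic genes 0.87. Hypoxia and glycolysis genes had a median of 0.46 (bounded 0.40), with 11 of 39 higher and 5 lower. The mitophagy gene BNIP3 was at least 101-fold lower, and CA9 and CA12, carbonic anhydrases, at least 92.8-fold and at least 76.8-fold higher. Cell cycle genes had a median of −0.22, which turned to 0.16 with arrays centred on their medians.

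The remaining lists lay inside the central 95% of random lists. Their medians were −1.03 for innate defence (bounded −0.81), −0.53 for the TGF-beta and BMP pathway, −0.31 for cytokines, −0.29 for p53 targets, −0.19 for the Notch pathway, −0.15 for NF-kB targets, −0.06 for ER and amino acid stress, 0.02 for Wnt genes and 0.19 for reference genes. The innate defence median was 1.52 when genes had to be above background on both arrays. Apart from innate defence and the TGF-beta list, each of these changed sign under at least 1 other scaling. For cytokines, p53 targets, the Notch pathway and ER and amino acid stress, the only such scaling was centring on the array medians. Blood cell markers had a median of 0.12, which also changed sign, and endothelial markers 1.44 (bounded 0.10), but −0.36 with no filter on dim probes. Of the fibroblast markers 2 of 11 were measured, COL1A1 at least 35.2-fold lower and FAP at least 6.13-fold higher.

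Spot noise gave an SD of 0.107 for a log2 difference, and the differences across genes above background on both arrays had an SD of 1.30. In 3420 genes with several probes the median SD between probes was 0.24, and in 17 of them probes differed by 2-fold in opposite directions. Centring each array on its median raised all differences by 0.38 and turned the split from 45.5% higher to 63.6% higher (4359 against 2495). The median signals of the wild-type and labelled SLPI-deficient arrays (21.3 and 19.5) lay near their lowest signals well above background (21.0 and 19.4). This setting thus centred the arrays on dim spots. The count of lower genes was 2030 when only genes above background on both arrays were used. Over all settings the list medians nearest to 0 were −2.38 for squamous, 2.01 for intestinal, 1.98 for HOX, 0.44 for mucin, −0.36 for mesenchymal, −0.27 for matrix protease, −0.30 for integrin, −0.54 for interferon-stimulated, −0.48 for MHC, 0.66 for EGF pathway, 0.39 for NRF2 and 0.45 for ribosomal genes.

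The second comparison set the colorectal line against the oral line. HT-29 had higher intestinal and HOX genes and lower squamous genes than wild-type Ca9-22. KRT6A and KRT5 were at least 4333-fold and at least 3057-fold lower in HT-29, and MIR205HG, the host gene of a microRNA of stratified epithelia, at least 2297-fold lower. The lowest log2 value well above background was −4.48 in HT-29 and −4.06 on the labelled SLPI-deficient array. Bounds for lower genes therefore reach further in HT-29, and larger bounds do not show lower expression than on the labelled array. LGALS4 was at least 1128-fold higher, PHGR1 at least 560-fold and KRT20, the intestinal keratin, at least 431-fold higher. Of 16940 genes compared, 2765 were at least 2-fold higher and 3648 at least 2-fold lower, or 37.9%.

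Squamous genes were lower in 33 and higher in 3 of 43 cases (median −4.94, bounded −4.12), and intestinal genes higher in 35 and lower in 3 of 52 (median 3.59, bounded 3.14). HOX genes were higher in 21 and lower in 4 of 29 cases (median 3.63, bounded 3.17), and mucin and secretory genes had a median of 2.75. S100P (2108-fold), CLDN3 (817-fold), PRSS2 (381-fold), a trypsinogen, and AGR2 (323-fold) had the highest differences measured on both arrays. ANXA8L1 (3463-fold, uncertain as above), PTPRS (339-fold), HCLS1 (268-fold) and VAV3 (200-fold) had the lowest. ACKR3, an atypical chemokine receptor, was at least 1842-fold lower, while the chemokine receptor CXCR4 was at least 260-fold higher.

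Protease inhibitors were again split, 13 higher and 13 lower of 34; the median was 0.25, the bounded median −0.02 and the median with no filter on dim probes −0.67. SPINK1 was at least 3342-fold higher, and SERPINB13 at least 97.2-fold lower. Matrix proteases had a median of −0.73, with 19 of 43 lower and 12 higher, MMP7 at least 1012-fold higher and the kallikrein KLK5 at least 103-fold lower. Matrix genes were lower in 26 and higher in 5 of 39 cases (median −1.96, bounded −1.85), and mesenchymal genes lower in 16 and higher in 4 of 26 (median −2.12, bounded −2.01). Interferon-stimulated genes were lower in 31 and higher in 3 of 45 cases (median −1.73, bounded −1.41), with IFITM3 24.2-fold lower. MHC genes had a median of −1.15 and metallothioneins −1.86. Cell cycle genes had a median of 0.65, with 17 of 54 higher and 1 lower, and CCNB1, cyclin B1, was 4.56-fold higher (log2 1.43 to 2.19 over its probes). The EGF pathway list had a median of 0.67, ribosomal proteins 0.50, sterol and lipid synthesis 0.43, NRF2 and xenobiotic genes 0.52 and junction genes 0.36 (bounded 0.24). FADS1, a fatty acid desaturase, was 179-fold lower. Endothelial markers had a median of 1.98 (bounded 0.70) over 6 genes, but −0.74 with no filter on dim probes.

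The innate defence median was −0.81, but 0.84 with only genes above background on both arrays. The Wnt median was 0.31 (bounded 0.10) and the NF-kB median 0.03, but −0.37 and −0.049 with no filter on dim probes. Blood cell markers had a median of −0.54, or −0.070 with arrays centred on their medians. Medians that changed sign under another scaling were −0.41 for integrins and adhesion receptors, −0.28 for the motility list, 0.07 for cytokines, −0.29 for the Notch pathway, −0.32 for the TGF-beta and BMP pathway, −0.37 for p53 targets, −0.20 for hypoxia and glycolysis, −0.07 for ER and amino acid stress and −0.08 for reference genes. For integrins, motility, Notch, TGF-beta, p53 and hypoxia genes, the only scaling that changed the sign was centring on the array medians. Of the fibroblast markers, COL1A1 was 33.2-fold lower and FAP at least 3.48-fold higher.

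Centring on medians raised all differences by 0.47 and turned the split from 43.1% higher to 65.2% higher (4557 against 2435). Choosing each probe without the labelled SLPI-deficient array, a setting chosen after seeing the data, gave 2760 higher and 3660 lower genes. Over all settings the list medians nearest to 0 were −2.10 for squamous, 1.60 for intestinal, 2.04 for HOX, 0.24 for mucin, −0.098 for mesenchymal, −0.27 for matrix protease, −1.06 for interferon-stimulated, −0.68 for MHC, 0.40 for EGF pathway, 0.18 for junction and 0.35 for NRF2 genes.

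The array labelled SLPI-deficient and the HT-29 array were nearer to each other than either was to wild-type Ca9-22. Of 16137 genes compared, 1027 were at least 2-fold higher and 1145 at least 2-fold lower in HT-29, or 13.5%, and the SD of the differences was 0.66. In HT-29 the median of the cell cycle list was higher, and those of the hypoxia and glycolysis list and the interferon-stimulated list were lower. Most members of each of these lists differed by less than 2-fold. Every direction in this pair rests on the labels of both arrays, and an exchange of these labels was not tested. BST2, tetherin, an interferon-induced membrane protein read at chromosome 19, positions 17513748 to 17513807 in the files, was at least 416-fold lower in HT-29. The DNA repair nuclease subunit EME1 was 50.4-fold higher.

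In this pair 19 of 54 cell cycle genes were higher in HT-29 and 2 lower (median 0.66, percentile 100), among them CDC20 (3.63-fold), AURKB (3.29-fold) and PLK1 (2.82-fold), which act in mitosis. CDKN1C, a cyclin-dependent kinase inhibitor, was 5.82-fold lower. Of 38 hypoxia and glycolysis genes 8 were lower and 0 higher (median −0.58, percentile 0), with NDRG1 4.19-fold and lactate dehydrogenase LDHA 2.90-fold lower. Interferon-stimulated genes were lower in 9 and higher in 2 of 39 cases (median −0.50), with IFI27 7.11-fold lower. Intestinal genes went both ways, 7 higher and 12 lower of 52 (median −0.17), with CEACAM6 5.46-fold higher and TFF3 3.66-fold lower (log2 −1.99 to −0.38 over its probes). Mucin and secretory genes had a median of −0.37, with 9 of 23 lower. Squamous genes had a median of 0.34 (bounded 0.31), with KRT17 8.53-fold higher and SPRR1B at least 21.9-fold higher. HOX genes had a median of 0.33, with 2 of 26 past 2-fold. Matrix genes had a median of 0.37, but −0.24 with no filter on dim probes, and Wnt genes 0.27 (bounded 0.19), with WNT11 at least 17.1-fold higher. TGFB1 was 8.13-fold and BAMBI, a decoy receptor of that pathway, 14.3-fold higher. Metallothioneins had a median of 0.78, sterol and lipid synthesis −0.34 and ribosomal proteins −0.26, the last with 0 of 44 genes past 2-fold and a median of −0.021 after quantile normalization. Protease inhibitors had 6 higher and 5 lower of 27 and a median of −0.02, which changed sign under another scaling. The same held for the medians of matrix proteases (0.05), cytokines (−0.03), the EGF pathway list (−0.02), the Notch pathway (0.04) and the TGF-beta and BMP pathway (−0.02). The other medians were −0.29 for innate defence, −0.22 for MHC genes (nearest to 0 over all settings −0.13), −0.19 for integrins and adhesion receptors (−0.10), −0.16 for ER and amino acid stress (−0.072), −0.15 for reference genes (−0.053), −0.09 for NRF2 and xenobiotic genes (−0.000011), 0.04 for the motility list (0.027, highest 0.13) and 0.12 for p53 targets (0.037). Junction genes (0.03), NF-kB targets (0.03, bounded 0) and mesenchymal genes (0.13) had medians that turned to −0.0043, −0.15 and −0.28 with no filter on dim probes. Blood cell markers had a median of −0.44 (nearest to 0 −0.21) and endothelial markers 1.11 over 5 genes, which was 0.059 with no filter on dim probes. Of the fibroblast markers, FAP was 1.76-fold lower and COL1A1 at least 1.06-fold higher.

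RAMP1 (91.9-fold), which partners the calcitonin receptor-like receptor, and COXFA4L2 (21.1-fold) had the lowest differences in HT-29, and ALCAM, an adhesion molecule, was 14.8-fold lower. LNCAROD (45.3-fold) and DMKN (29.8-fold) were among the highest, and CAV1, caveolin 1, was at least 31.8-fold higher. With normexp background correction the counts were 493 higher and 495 lower. Centring on medians turned the split from 47.3% higher to 55.8% higher (1220 against 968). Over all settings the medians nearest to 0 were 0.15 for squamous, −0.086 for intestinal, 0.21 for HOX and 0.076 for Wnt genes.

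Both differences from wild-type Ca9-22 could be compared in 16179 genes. Of these, 2018 were higher and 2792 lower on both other arrays, and 23 were opposite. Independent lists of these sizes would share 454 and 775 genes. Simulated unchanged arrays sharing the wild-type array gave at most 3 and 6. The simulation covered only the 13023 genes above background on all arrays, so dim genes did not enter it. Of the genes past 2-fold on the array labelled SLPI-deficient, 77.5% were past it in the same direction in HT-29. Across 13023 genes above background on all arrays, Pearson's correlation of the differences was 0.88, against 0.50 in the simulation, and their covariance 1.40, against 0.016. Genes are not independent replicates, and part of the excess over independent lists may come from the shared array, which cannot be split.

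**Figure D2:**
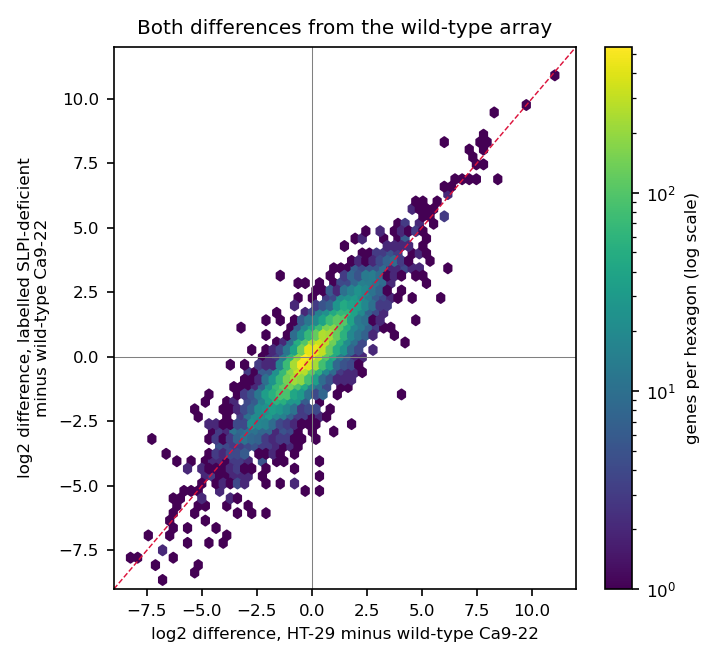
Log2 difference from wild-type Ca9-22 for HT-29 (x axis) and for the array labelled SLPI-deficient (y axis), over the 13023 genes above background on all 3 arrays. Colour gives the number of genes per hexagon on a log scale, and the dashed line marks equal differences; genes spread along that line, with a correlation of 0.88.

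**Figure D3:**
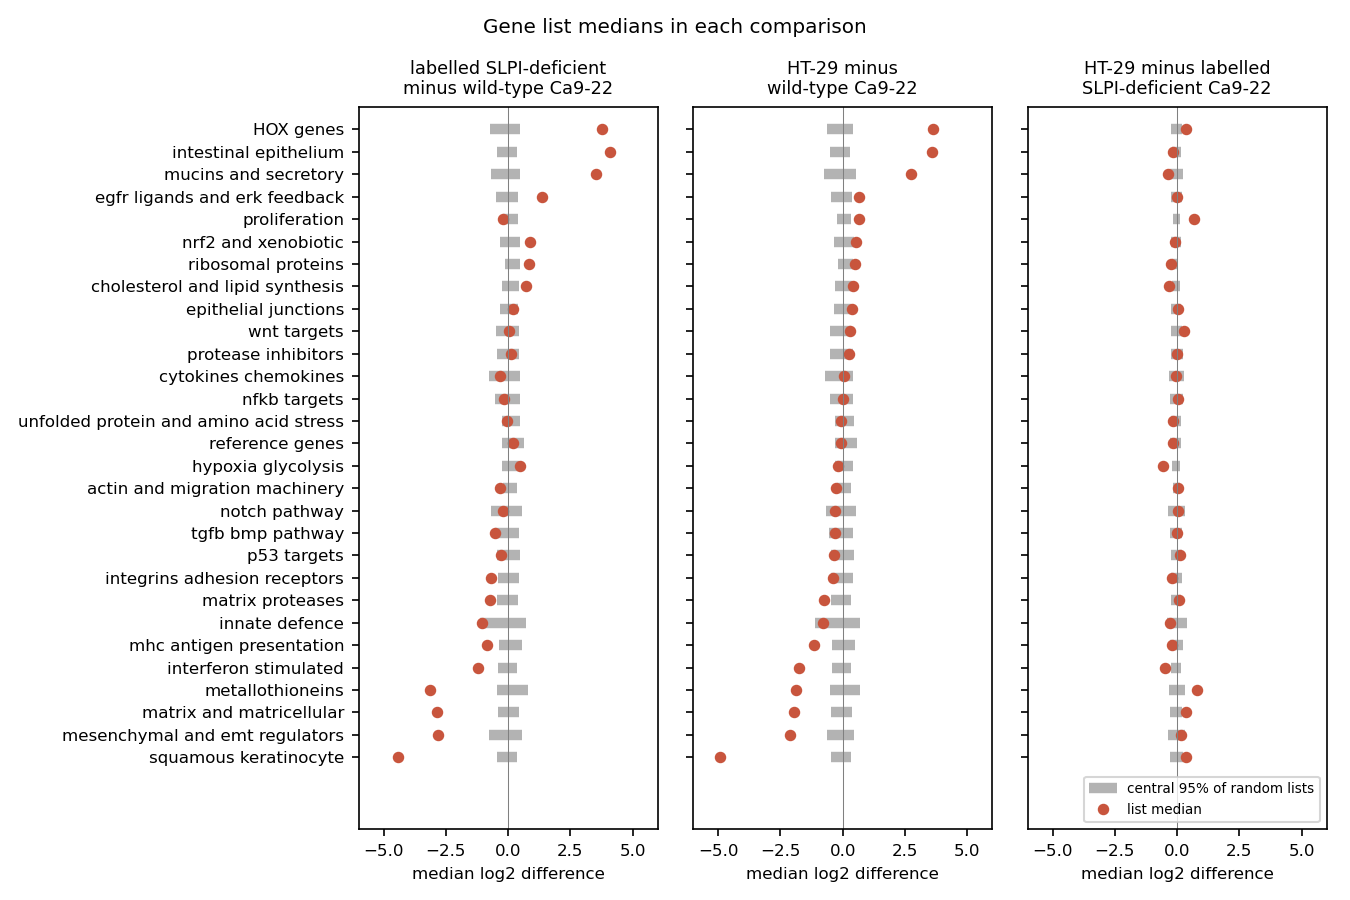
Median log2 difference (x axis) of the gene lists (y axis), without the markers of fibroblasts, blood and endothelial cells, in the 3 comparisons, as red points, with the central 95% of 10000 random lists matched on expression as grey bars. Squamous, matrix and mesenchymal lists lie below and intestinal and HOX lists above the bars in both comparisons with wild-type Ca9-22, while the medians shown for HT-29 against the labelled array lie between −0.58 and 0.78.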

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

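Every setting here was fixed before the data were examined except the choice of probes without the labelled SLPI-deficient array. No paired analysis was possible because each group has 1 array and no result comes from a test. Signal over background limits the dim genes, for which bounds depend on the lowest signal well above background.

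Counts are given for the labelled SLPI-deficient array against wild-type Ca9-22 (comparison A), HT-29 against wild-type Ca9-22 (B), HT-29 against the labelled SLPI-deficient array (C) and genes shared by A and B. Normexp background correction gave 2178 lower genes in A, 2411 lower in B, 493 higher and 495 lower in C and 1754 shared lower genes. Its offset pulls dim values together, but the cause was not tested. Centring on the median gave 4359 and 4557 higher genes in A and B and 3271 shared higher genes. This setting adds 0.38 and 0.47 to all differences, while no other scaling shifted their median by more than 0.038 in A and 0.024 in B. Only 48.5%, 48.4% and 50.3% of spots were well above background on the wild-type, labelled SLPI-deficient and HT-29 arrays. The array medians therefore lay near the detection floor, and sign changes under this setting alone are weak evidence of fragility. Counting only genes above background on both arrays gave 2030, 2164 and 712 lower genes in the 3 comparisons and 1403 shared lower genes, since fewer genes are counted. With no filter on dim probes there were 5584 lower genes in B and 1930 higher and 2642 lower in C, since more genes are counted. At 1.5-fold there were 4524, 4294 and 2303 higher genes in the 3 comparisons, 2710 lower in C and 3214 shared higher genes. At 4-fold there were 1114 higher and 1530 lower genes in A, 1097 and 1629 in B, 225 and 233 in C, and 823 and 1243 shared. All other counts stayed within 1.5 times the main count.

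The SLPI difference stayed below 0 under every setting run. In A it was −1.87 with normexp, −2.12 with quantile normalization and −1.62 with median centring. In B it was −3.67 with normexp and −3.60 with median centring, and in C −1.80 with normexp. The other settings moved it by less than the spot SD.

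Of 741 list medians recomputed under these settings, 489 moved by less than the spot SD of a difference, 249 moved by more and 3 of those beyond 2-fold reversed. Innate defence in A was 1.52 when genes had to be above background on both arrays, since dim genes left the list. Endothelial markers were −0.36 in A and −0.74 in B with no filter on dim probes, where genes below background entered. Of 3041 values of named genes, 1965 stayed within that SD, 1074 moved and 2 reversed: PLAU (−0.024) and PKP1 (0.10) in C, with the mean of a gene's probes. The cause was not tested.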

Other observations

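The gene families and the tests of exchanged, HT-29-like or mixed RNA, of cycling cells and of quantile-normalized lists were chosen only after results were seen. Quantile normalization itself was a planned setting. UDP-glucuronosyltransferases, which conjugate drugs and steroids, were higher than in wild-type Ca9-22 in 6 of 6 genes on the array labelled SLPI-deficient (median 3.75, bounded 3.47) and in 4 of 6 in HT-29 (median 2.64, bounded 2.11). They were lower in HT-29 than on the labelled array, with a median of −1.65 and 4 of 6 past 2-fold. UGT2B10 was at least 19.0-fold and UGT1A6 12.7-fold higher on the labelled array than in wild-type Ca9-22, but UGT1A and UGT2B members are near-identical and their probes may not tell them apart; under the other scalings the 3 medians kept their signs, and the alternatives nearest to 0 were 2.23, 0.91 and −0.99 in this order.

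DLX homeobox genes, regulators of jaw and skin development, were lower than in wild-type Ca9-22 in 5 of 6 genes on the array labelled SLPI-deficient (median −3.77, bounded −2.38) and in 6 of 6 in HT-29 (median −4.53, bounded −3.51). DLX1 stood apart: its log2 difference was −0.33 on the labelled array, and in HT-29 it was at least 11.3-fold lower. Protocadherin beta genes, a cluster of similar adhesion genes whose probes are uncertain, were lower in 6 of 7 and 7 of 7 genes (medians −3.92 and −5.45, bounded −2.74 and −3.34). Bounds reach further in HT-29 than on the labelled array, so part of its more negative bounded medians may come from that. LYPD genes were lower in 5 of 6 genes on both arrays (medians −2.69 and −3.90), and TCEAL genes in 4 of 7 and 6 of 7 (medians −1.40 and −1.21). Under the other scalings these medians kept their signs, and those nearest to 0 were −1.51 and −2.025 for DLX, −1.71 and −1.78 for protocadherin beta, −1.38 and −1.75 for LYPD and −1.02 and −0.75 for TCEAL genes.

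Of 1363 genes at least 8-fold apart between HT-29 and wild-type Ca9-22, 1291 (94.7%) lay nearer to HT-29 on the array labelled SLPI-deficient, and 72 lay nearer to wild-type Ca9-22. SLPI lay about midway, −2.00 from wild-type Ca9-22 and −2.07 to HT-29, and nearer to HT-29 with normexp background correction (−1.87 and −1.80). The 72 included the inositol phosphatase INPP5D (log2 level 1.64 in wild-type Ca9-22, 2.05 on the labelled array and below background in HT-29) and SSBP2. Among the 23 genes that differed from wild-type Ca9-22 in opposite directions, BST2 was at a log2 level of 0.01 in wild-type Ca9-22, 4.22 on the labelled array and below background in HT-29. TP73 was at −1.80, −0.47 and −3.10, and EME1 at 0.47, −1.04 and 4.62.

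The array labelled SLPI-deficient Ca9-22 had high intestinal and low squamous transcripts. An exchange of the wild-type and HT-29 labels is argued against, since the intestinal median was 3.59 higher in HT-29 than in wild-type Ca9-22. A mixture with 10% or more of wild-type Ca9-22 RNA is argued against as well: of 32 genes bright in wild-type Ca9-22 and below background in HT-29, 29 were below background on the labelled array, and the median upper bound was 0.311% of the wild-type level (highest 1.31%). An exchange of the HT-29 and SLPI-deficient labels was not tested. Intestinal genes cannot tell it, since 50 and 46 of 66 were well above background on the arrays so labelled. Such an exchange would swap the first 2 comparisons and turn every direction of the third. RNA of an HT-29-like line under the SLPI-deficient label is a candidate explanation. Outside all gene lists, 1073 of 1130 genes that differ 8-fold between HT-29 and wild-type Ca9-22 (94.96%) lay nearer to HT-29. These genes are part of the 1363 above, so this share restates that result and decides nothing. Cells that had changed to an HT-29-like state would give it too. Whether such RNA would be from HT-29 itself or another intestinal line stays open. Whether loss of SLPI could bring Ca9-22 cells to this state also stays open and untested with 1 array per group.

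HT-29 had a higher median of the cell cycle list and a lower median of the hypoxia and glycolysis list than the array labelled SLPI-deficient. No list held glycolysis genes alone. A brightness-dependent difference between arrays is argued against, since after quantile normalization the medians were 0.65 and −0.51, at percentiles 100 and 0 of matched random lists. Fewer cycling cells in the labelled culture and a difference between lines cannot be told apart. The 26 mitotic members had a median of 1.08 (percentile 100) and the 20 S-phase members 0.41 (percentile 99.96), but both are parts of the list that showed the difference and so decide nothing. The labels give the number of cells seeded but not the density at harvest.

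Ribosomal protein genes were higher on the array labelled SLPI-deficient than in wild-type Ca9-22, with a median of 0.85. HT-29 shared this direction, with a median of 0.50 against wild-type Ca9-22. After quantile normalization the labelled array's median was 0.45, at percentile 99.93 of matched random lists. That percentile argues against a brightness-dependent difference as the whole cause. At the same setting the HT-29 median was 0.43 against wild-type Ca9-22 and −0.021 against the labelled array. A higher median than in wild-type Ca9-22 was thus not particular to the labelled array. In the main setting it was larger there: 18 of 44 genes were at least 2-fold higher, against 4 of 44 in HT-29. The median of HT-29 against the labelled array was −0.26 at that setting. The doubt about the label applies here too, and no biological explanation was tested.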
